A study of Drosophila melanogaster with 4 samples.

How the data were processed

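Gene expression in whole Drosophila melanogaster females was measured with 4 Affymetrix DrosGenome1 arrays, 2 for flies treated with juvenile hormone III (JH III) in acetone and 2 for flies treated with acetone. Groups and replicate numbers were taken from the sample titles. The deposited values are 1 linear intensity per probe set and array. Their 2% trimmed means were 500.1 in each array, the form of Affymetrix signals scaled to a common target, and the software that summarised probe pairs is not given in the sources used here. RNA was extracted with Trizol and chloroform and the target carried biotin, per the labels. A deposited description file for each array gave the array type, wash protocol, chip lot, fluidics module and scan order, and no expression values.

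The table held 14010 probe sets, of which 44 were Affymetrix controls. Of the remaining 13966, 12442 had 1 gene symbol in the platform annotation, 327 had several and 1197 had none, and only those with 1 symbol were named. Through their Entrez numbers 12393 matched a RefSeq gene table (assembly Release 6 plus ISO1 MT), which was used for names only, and 0 symbols changed. These stand for 10843 genes, 1209 of them with more than 1 probe set. No coordinates are given, because the sources used here name no genome build for the arrays.

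Because the arrays' trimmed means were already equal, the values were kept as scaled by the authors. They were tested as log2(signal + 83), where the pseudocount 83 is the 25th percentile of all values. Differences on this scale are understated for probe sets of low signal. The lowest 25% of probe sets by mean over all 4 arrays were left out, leaving 10475. limma version 3.58.1 in R 4.3.3 was used (lmFit, then eBayes with a trend in the variance, two-sided) for JH III minus acetone, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. The fit had 2 residual degrees of freedom per probe set and 66.9 after moderation. Replicates are separate pools of females on separate arrays, so that the spread behind the p-values includes both. Most of that spread was borrowed from other probe sets, as the 66.9 against 2 degrees of freedom show. A probe set was taken as above background where it exceeded the 95th percentile of 23 unspiked control probe sets on that array, which was 369 and 240 in the JH III arrays and 139 and 295 in the acetone arrays. Where a group was below this level on both arrays and the other above it on both, the fold was given as a bound ("at least"), with each low value raised to that level and no pseudocount.

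The gene lists, the rule for named genes, the tests and the alternatives were fixed before the data were examined, except for those said to have been chosen later. There were 34 lists. List tests took 1 probe set per gene, the one with the highest mean, and included genes of low signal. List members below the filter had no limma test of their own. Counts of members called, under an unadjusted p or without overlap between groups leave them out. They used camera with a preset correlation of 0.01 and with an estimated correlation, and fry. With 4 arrays the estimated correlation rests on 2 residual degrees of freedom, and 0 of the 34 lists passed with it (lowest adjusted p 0.873). Each list's median was also placed among 10000 random lists of the same size, drawn for each member from the 200 genes nearest in mean signal. Named genes were every measured antimicrobial peptide, the 12 higher and 12 lower genes of largest difference past the threshold with no overlap between groups (filled by smallest unadjusted p where fewer passed), up to 4 genes of smallest p from every other list, and 9 hormone-response and yolk genes. The per-peptide t-test that the labels name was run as an alternative on the same log2 values and is called the methods' t-test.

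The fits were tested on simulated arrays with the means and moderated spread of the real comparison and 10475 probe sets. Of probe sets changed 2-fold, 4-fold, 8-fold and 16-fold, 6.12%, 46.9%, 78% and 94% were called, and 4 of 10277 unchanged ones were. A list of peptides shifted down by 1 log2 unit was recovered at -0.93 with 0 of 33 other lists called. The simulated noise was independent between probe sets and alike in all arrays, as the fit assumes. The real arrays were not alike, and a split of them that crosses the treatments gave 5 lists past camera with a preset correlation. The simulated rates are therefore no measure of the error in the real arrays.

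Alternatives were a pseudocount of 1 or of the median of all values (256), quantile normalization, centring each array on its median, no filter or a filter of 50%, eBayes without a trend, the methods' t-test, the replicate number as a block, the mean of all probe sets of a gene in the list tests, and each array left out in turn. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for reading and plotting.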

Results

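Transcript levels in whole adult female Drosophila melanogaster were measured 12 hours after juvenile hormone III (JH III), a sesquiterpenoid hormone of insects, was applied to the body surface. The flies were Y/W by the sample titles, read here as y, w, a laboratory strain with yellow body and white eyes. They had gone without yeast for the first 5 days of adult life, a diet that the labels give as a means of lowering the flies' own hormone. Each fly received 0.1 µl of fluid, either acetone alone or acetone carrying JH III at 187 mM, which comes to 18.7 nmol per fly. There were 4 RNA samples, 2 per treatment, each from a separate pool of 30 females per the labels and each measured on 1 Affymetrix DrosGenome1 array. The number of arrays, 2 per group, limits the precision of every value. After control probe sets and the lowest 25% by mean signal were set aside, 10475 probe sets naming 8455 genes were tested. The labels put 1 question to these arrays, whether the hormone lowers the expression of antimicrobial peptides.

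The measured antimicrobial peptides were lower in the JH III females as a group. These are the small secreted peptides that the fat body and epithelia of flies release against bacteria and fungi. Most of the planned list, with AttA, AttB, AttC, DptA, Dro and most cecropins among it, had no probe set naming 1 gene alone. The 10 measured members therefore do not stand for the whole family. Of the 10 measured members, 9 lay below the acetone level and 8 were lower in both JH III arrays than in both acetone arrays. These 8 include AttD and Anp, which were under the control level in both JH III arrays and for which no fall could be bounded. The mean difference of the list was -0.69 on the log2 scale (SE 0.25 over members). The control genes GAPDH and eIF-4a, described below, had lower ratios of 3' to 5' signal in both JH III arrays than in both acetone arrays. DptB, a diptericin controlled by the Imd pathway, fell from a signal of 19659 ± 4266 to 5438 ± 537 (SD, n = 2 each), a log2 difference of -1.82 ± 0.37 (SE, limma adjusted p = 0.0136). Metchnikowin (Mtk, -1.23 ± 0.42 SE) and Listericin (-1.10 ± 0.41 SE) passed with p adjusted over the list alone, at 0.0243 and 0.0285. Over all genes tested they did not (limma adjusted p = 0.401 and 0.476).

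**Figure D1:**
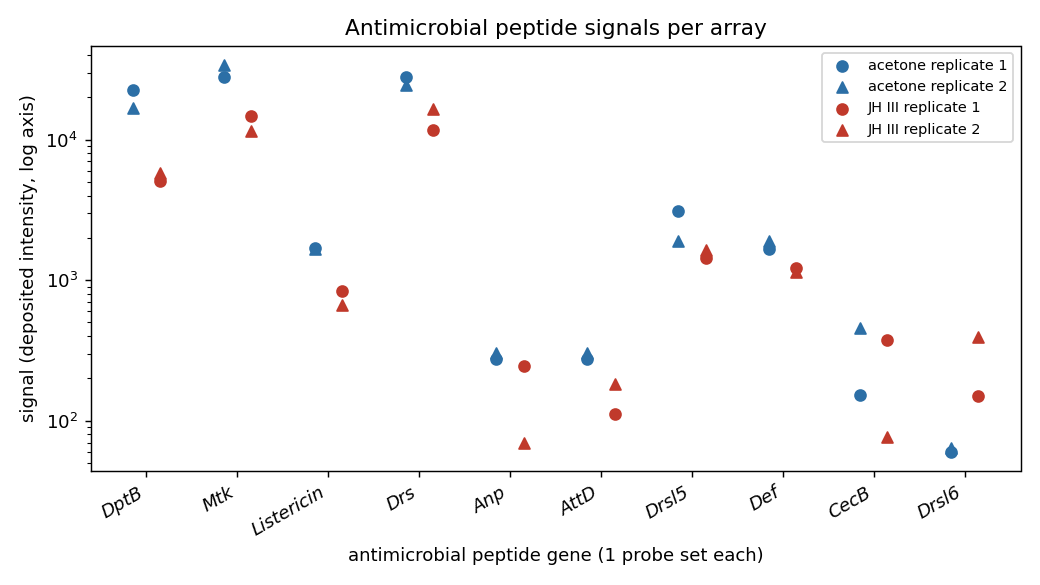
Deposited signal (linear intensity on a log axis) of each of the 10 antimicrobial peptide genes, 1 point per array, with acetone in blue and JH III in red, circles for replicate 1 and triangles for replicate 2. DptB, Mtk, Listericin and Drs have both JH III points below both acetone points, and Drsl6 has them above.

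Over all genes tested, 1 of the 10 peptides fell (DptB) and 0 rose, and adjusted over the list alone 3 fell and 0 rose. The 3 became 1 under quantile normalization or with the replicate block, and 0 without a trend in eBayes. With the other pseudocounts and filters and with median centring they stayed 3. At an unadjusted limma p under 0.05 there were 4, all lower. The last of these was drosomycin (Drs), the antifungal peptide of the Toll pathway, with 26238 ± 2574 in acetone and 14101 ± 3348 with JH III (SD, n = 2 each; log2 difference -0.91, unadjusted p = 0.0334). Defensin (Def, -0.55), Drsl5 (-0.63), AttD (-0.70), Anp (-0.73) and CecB (-0.41) did not pass, and for AttD and Anp, under the control level in both JH III arrays, no fold above 1 could be bounded. Nor did Drsl6, the member with a positive difference (1.2), at 62.3 ± 2.75 in acetone and 271 ± 171 with JH III (SD, n = 2 each). By the methods' t-test 4 peptides (DptB, Listericin, Def and Mtk) had an unadjusted p under 0.05 and 0 passed after Benjamini-Hochberg adjustment over the list, where the lowest value was 0.0811. The list passed camera, limma's competitive gene set test, with a preset correlation between genes (adjusted p = 8.36e-05 over 34 lists). It did not pass with the correlation estimated from the 4 arrays (adjusted p = 0.873 with an estimated correlation). fry, limma's test of whether a list moves one way on balance, gave an unadjusted p of 0.0062 and an adjusted p of 0.153. The mean log2 level of the list was 10.31 and 10.21 in the JH III arrays and 10.92 and 10.98 in the acetone arrays. An exact two-sided permutation test of these list means gave p = 0.333, which is the smallest p that 2 arrays against 2 allow. JH III replicate 1 stood apart from the other arrays, as described below, and without it the mean difference of the list was -0.74 (camera adjusted p = 0.000602).

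The other immune lists did not pass camera. For the 8 Bomanins and other secreted peptides induced by infection the camera adjusted p was 0.381. Of these 0 passed over all genes and 2 fell adjusted over the list alone, BomBc2 (-1.12 ± 0.35 SE) and BomBc3 (-1.02 ± 0.37 SE), the same 2 that had an unadjusted limma p under 0.05. BomS6 (0.49) and BomS4 (0.34) had positive differences. In 5 further lists limma called 0 members over all genes and 0 adjusted over the list alone. These were the 9 peptidoglycan and glucan recognition proteins (mean difference -0.18, camera adjusted p = 0.398), the 23 Toll and Imd pathway components (0.10, 0.969) and the 12 genes of the prophenoloxidase cascade of melanin formation (-0.12, 0.554). The others were the 6 lysozymes (0.06, 0.937, with a median at percentile 99.16 of matched random lists) and the 6 Turandot and JAK/STAT response genes (0.13, 0.968). At an unadjusted p under 0.05 stood PGRP-SB1 (-0.84) of the first, Dif (1.83) of the second and Spn27A (-1.59) of the third, and none of the last 2.

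Over the whole array 17 probe sets passed an adjusted p of 0.05 by limma, 3 higher and 14 lower with JH III, and in all 17 the groups did not overlap. The strongest named gene was Diedel, which encodes a small secreted immune-modulating protein. Its signal was 5926 ± 2881 with JH III and 120 ± 85.2 in acetone (SD, n = 2 each), a log2 difference of 4.87 ± 0.44 (SE, limma adjusted p = 8.56e-13). Both acetone arrays lay under the 95th percentile of unspiked control probe sets, so that Diedel was at least 27.4-fold higher with JH III against that level. A probe set with no gene symbol had a similar difference, 4.93, with 12119 and 15862 in the JH III arrays and 54.3 and 1440 in the acetone arrays (limma adjusted p = 2.82e-12). At an unadjusted p under 0.05 there were 764 probe sets, 371 higher and 393 lower, and after Benjamini-Hochberg adjustment the methods' t-test called 0, with 607 under 0.05 before it.

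The genes that fell included enzymes of energy and sugar metabolism. SdhB, the iron-sulphur subunit of succinate dehydrogenase, fell from 11492 ± 3518 to 3311 ± 1065 (SD, n = 2 each; log2 difference -1.77 ± 0.36 SE, limma adjusted p = 0.0136). Tps1, the trehalose-6-phosphate synthase that makes the blood sugar of insects, fell from 11982 ± 3219 to 4189 ± 2087 (-1.56 ± 0.37 SE, limma adjusted p = 0.0399). The aldehyde oxidase AOX1 (-2.15), the sterol-binding protein Npc2g (-1.66) and the mucin Mur18B (-1.52) also passed, with limma adjusted p of 0.0259, 0.0306 and 0.0399. The other named genes that fell by the rule for named genes were CG4363 (-2.32), CG42369 (-2.27), CG17108 (-2.21) and CG1648 (-1.65), the last 2 from signals of 63765 and 16660 in acetone. A second probe set of CG15353 passed (-1.94), and the brighter one of that gene did not (-0.70, limma adjusted p = 0.712). For Sarm, a NAD-cleaving enzyme known from axon degeneration, the probe sets disagreed, 1 of its 3 passing (at least 5.43-fold higher) and the brightest at -0.59 (limma adjusted p = 0.767). CG15353 and Sarm, and the unnamed probe set, lie outside the rule for named genes and were chosen after their values were seen. Without JH III replicate 1, limma called 3 probe sets, all 3 among the 17, and after quantile normalization or median centring 2 of the 17, both higher. Across 13 alternatives Diedel passed in 11, DptB and SdhB in 3 each, Tps1 and Mur18B in 1 each, and the other 6 called genes of the rule in 2 to 4.

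**Figure D2:**
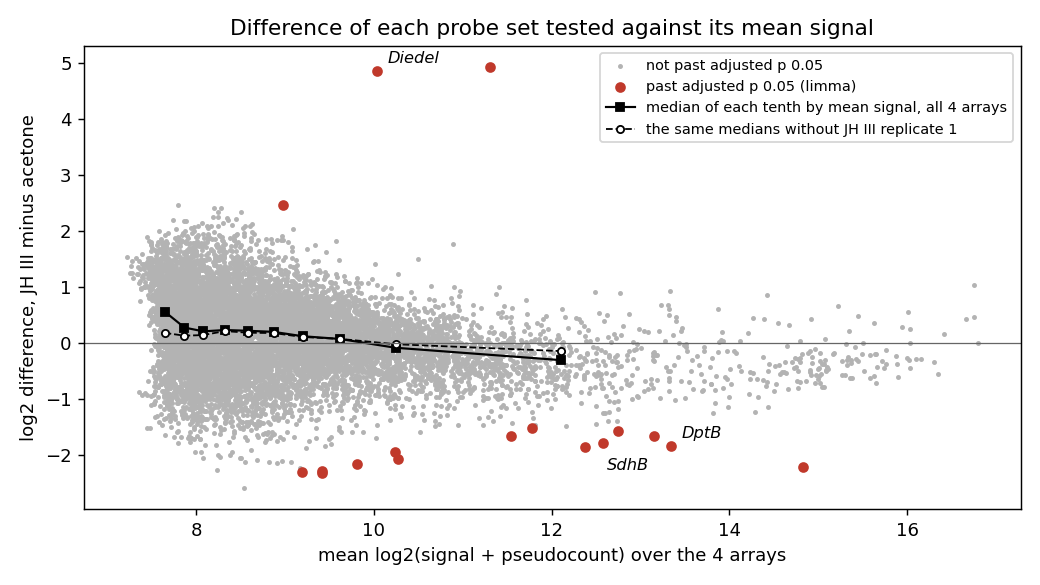
Log2 difference (JH III minus acetone) of each of the 10475 probe sets tested against its mean log2 level over the 4 arrays, with the 17 probe sets past a limma adjusted p of 0.05 in red. The black lines give the medians of 10 classes of mean signal, from 0.57 in the dimmest to -0.30 in the brightest with all 4 arrays (solid) and from 0.19 to -0.14 without JH III replicate 1 (dashed).

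Below the threshold, the higher genes of smallest p were CG6678 (1.83 ± 0.50 SE), CG42750 (2.04) and CG32813 (1.51), each with a limma adjusted p of 0.149. The next lower ones were the odorant-binding protein Obp99c (-1.48 ± 0.36 SE, limma adjusted p = 0.0543) and CG3088 (-1.42, 0.0648).

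Genes of the respiratory chain and ATP synthase were lower as a group. Of the 70 members of this list 61 lay below the acetone level and 39 were lower in both JH III arrays than in both acetone arrays (mean log2 difference -0.46, SE 0.06 over members). Over all genes 1 fell (SdhB) and 0 rose, and adjusted over the list alone 5 fell and 0 rose. Among them were the complex I subunits ND-75 (-1.32 ± 0.36 SE), ND-B18 (-1.2 ± 0.36 SE) and ND-ASHI (-1.15 ± 0.36 SE). The list passed camera with a preset correlation (adjusted p = 8.38e-14), and gave adjusted p = 0.873 with an estimated correlation. Without JH III replicate 1 its mean was -0.30 (camera adjusted p = 0.000108). After quantile normalization it was -0.23 (camera adjusted p = 0.000933). The median of random lists matched on mean signal was -0.23, against -0.54 for this list. In a split that crosses the treatments, JH III replicate 1 and acetone replicate 2 against the remaining arrays, the list's mean was -0.29. Its mean log2 level was 11.27 and 11.57 in the JH III arrays and 12.01 and 11.74 in the acetone arrays, in the same order as the ratio of 3' to 5' signal of GAPDH given below.

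Digestive enzymes and muscle proteins were also lower as lists with all 4 arrays. The 41 digestive serine proteases, amylases and maltases had a mean difference of -0.30 and 30 members below the acetone level (camera adjusted p = 0.00149, and adjusted p = 0.873 with an estimated correlation). The maltase Mal-A1 (-1.46 ± 0.38 SE) was the 1 member that passed adjusted over the list alone, and 0 passed over all genes. An unadjusted limma p under 0.05 was found for 6, all lower, including Mal-A4 (-1.36), Mal-A6 (-1.66) and Mal-A7 (at least 2.15-fold lower). The 17 muscle structural proteins had a mean of -0.36 (camera adjusted p = 0.00414, and adjusted p = 0.873 with an estimated correlation). Of these 0 were called over all genes or adjusted over the list alone, and 4 had an unadjusted limma p under 0.05, among them Prm (-1.24), Mlc1 (-0.94) and Mlp84B (-0.87). Without JH III replicate 1 the means were -0.18 and -0.14, and neither list passed (camera adjusted p = 0.249 and 0.425). Nor did they pass without acetone replicate 1 (0.114 and 0.792) or after quantile normalization (0.147 and 0.388). The mean log2 level of the digestive list was 10.50 and 10.74 in the JH III arrays and 11.07 and 10.78 in the acetone arrays, again in the order of the GAPDH ratio, and that of the muscle list (10.31 and 10.76, 11.17 and 10.63) was not. Of all 34 lists, 6 had a median below the 95% range of matched random lists and 2 above it, among them glutathione S-transferases (percentile 0.24), cytochrome P450 enzymes (0.79), mitochondrial ribosomal proteins (0.9), lysozymes and eggshell proteins, which did not pass camera. Of the 6, 3 were below it also without JH III replicate 1. The percentiles of the 5 named lists were then 1.16, 5.41, 20.4, 74.9 and 100, in the order given.

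**Figure D3:**
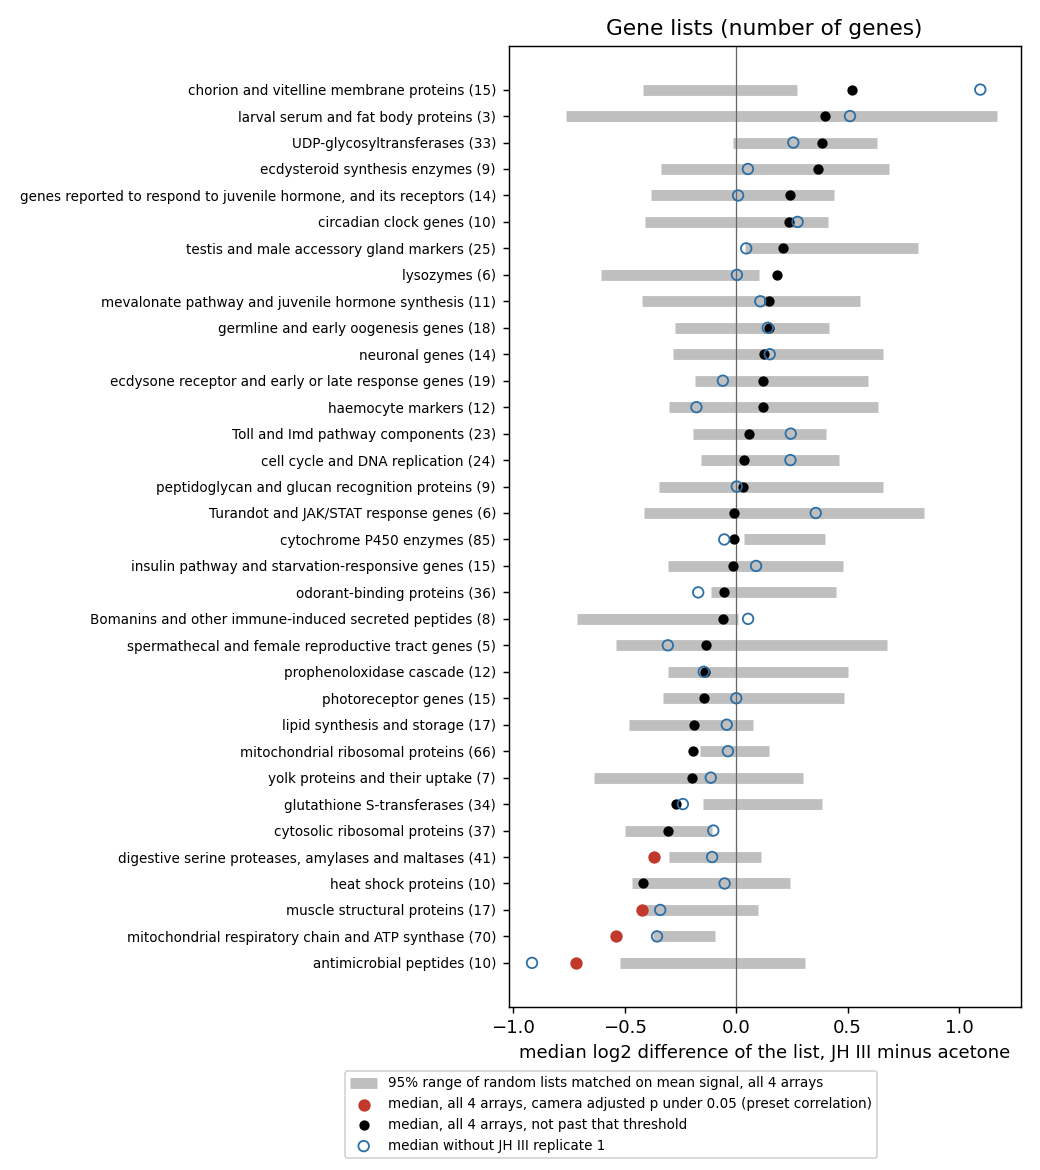
Median log2 difference (JH III minus acetone) of each of the 34 gene lists, with the number of genes in parentheses, filled for all 4 arrays (red where the camera test with a preset correlation passed) and open without JH III replicate 1. Grey bars give the 95% range of 10000 random lists of the same size matched on mean signal with all 4 arrays. The antimicrobial peptides lie at -0.72 and -0.91 and the respiratory chain genes at -0.54 and -0.35. The peptide median with all 4 arrays falls between Anp and AttD, for which no fall could be bounded.

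Other metabolic lists did not pass. In the 15 genes of the insulin and starvation list (mean -0.21, camera adjusted p = 0.421) 1 member passed adjusted over the list alone and 0 over all genes. This was the alpha-glucosidase tobi, named for its response to brain insulin (at least 2.78-fold lower, limma adjusted p = 0.112 over all genes). Its signal was 868 ± 376 in acetone and 70.0 ± 21.5 (SD, n = 2 each) with JH III, where both arrays lay under the control level. In 4 more lists limma called 0 members over all genes or adjusted over the list alone. The 17 genes of lipid synthesis and storage had a mean of -0.15 (camera adjusted p = 0.171), and 3 of them an unadjusted p under 0.05, the acetyl-CoA synthase AcCoAS (-0.91), the lipid droplet protein Lsd-1 (-0.75) and, in the other direction, the lipid synthesis regulator SREBP (1.15). The 10 heat shock proteins had a mean of -0.34 (camera adjusted p = 0.208), and 3 such members, the mitochondrial chaperone Hsp60A (-0.98), Hsp26 (-1.26) and Hsp27 (0.81). The 37 cytosolic and 66 mitochondrial ribosomal proteins had means of -0.21 and -0.18 (camera adjusted p = 0.0755 and 0.0775) and 0 such members each. Both passed with no filter (0.0321 and 0.0228), the cytosolic list also with the mean of all probe sets of a gene (0.0335) and the mitochondrial list after median centring (0.0152).

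Among detoxifying enzymes, the 34 glutathione S-transferases (mean -0.06, median -0.27, camera adjusted p = 0.28) had 1 member lower adjusted over the list alone, GstT3 (-1.69 ± 0.47 SE), and 0 over all genes. Another 3, GstT4 (at least 2.47-fold lower), GstD1 (-0.97) and GstE12 (-0.90), had an unadjusted limma p under 0.05. The 85 cytochrome P450 enzymes (mean -0.04, camera adjusted p = 0.443) and the 33 UDP-glycosyltransferases (0.23, 0.607) had 0 members called either way, with 60 and 22 of them above the filter and tested. In each, 3 had an unadjusted limma p under 0.05, with Cyp28d1 (-2.10), Cyp6d5 (-1.27), Ugt36D1 (at least 2.43-fold lower) and Ugt37A3 (1.78) among them.

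Known hormone-response and yolk genes gave no call, but several were near background. Kr-h1 and jhamt exceeded the level of unspiked controls in 0 acetone arrays and 1 JH III array. For gce it was 1 acetone array and 0 JH III arrays, and for Met and usp 1 array of each group. A change in these genes could be missed here. The juvenile hormone target Kr-h1 had a log2 difference of 0.94 ± 0.80 (SE, limma adjusted p = 0.825), with signals of 252 and 320 in the JH III arrays and 23.7 and 262 in the acetone arrays. The receptors Met and gce were at 0.49 and -0.09. The hormone synthesis enzyme jhamt was at 1.48 ± 0.95 (SE), with a signal of 624 in JH III replicate 1 and 23.0 in replicate 2. The ecdysone receptor subunits EcR and usp were at 0.51 and 0.36. The yolk protein transcripts Yp1, Yp2 and Yp3 were at -0.27, 0.04 and -0.42, with 95% intervals of -1.2 to 0.66, -0.79 to 0.87 and -1.39 to 0.55. In the 5 lists around these genes limma called 0 members over all genes or adjusted over the list alone. These were the 14 hormone-response genes and receptors (mean 0.21, camera adjusted p = 0.937), the 11 genes of the mevalonate pathway and hormone synthesis (0.10, 0.937) and the 19 ecdysone-response genes (0.23, 0.749). The last 2 were the 9 ecdysteroid synthesis enzymes (0.46, 0.282) and the 7 genes of yolk and its uptake (-0.17, 0.523). At an unadjusted limma p under 0.05 were Jheh2 (-0.98), Aldh-III (-1.15), ftz-f1 (1.07) and ImpE2 (at least 1.99-fold higher), and none of the last 2 lists.

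Eggshell genes varied with the arrays used and did not pass camera. Of the 15 chorion and vitelline membrane proteins 12 lay above the acetone level, 3 were higher and 1 lower in both JH III arrays than in both acetone arrays, with a mean of 0.49 (camera adjusted p = 0.162) and a median at percentile 99.94 of matched random lists. Over all genes 0 were called, with 5 at an unadjusted limma p under 0.05. Adjusted over the list alone 2 rose, Cp15 (1.77 ± 0.57 SE) and Vm26Ac (at least 2.32-fold, being under the control level in both acetone arrays), and 1 fell, Cp16 (-1.48 ± 0.49 SE). For Cp15 the acetone arrays held 5747 and 99.3, on both sides of the JH III arrays (4261 and 2757). The list's mean was 0.91 without JH III replicate 1 (camera adjusted p = 0.000263) and 0.71 without acetone replicate 1 (7.56e-05), but 0.07 without JH III replicate 2 (0.856) and 0.27 without acetone replicate 2 (0.721). The 18 germline genes (0.15, camera adjusted p = 0.749), the 24 genes of the cell cycle and DNA replication (-0.01, 0.937) and the 5 genes of the spermathecae and female tract (-0.25, 0.554) had 0 called either way. Among their members otu (1.32), Orc1 (1.06) and E2f1 (at least 1.94-fold lower) had an unadjusted limma p under 0.05.

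Markers of other tissues and cell types, in 7 lists, did not pass camera. Of the 36 odorant-binding proteins (median -0.05, adjusted p = 0.398) 2 fell adjusted over the list alone, Obp99c and Obp56d (-1.15 ± 0.38 SE). Over all genes 0 did, with 4 at an unadjusted limma p under 0.05. In the other 6 limma called 0 members over all genes or adjusted over the list alone. Of these, the 12 haemocyte markers (mean 0.26, adjusted p = 0.815), the 3 larval serum and fat body proteins (0.42, 0.607) and the 14 neuronal genes (0.17, 0.815) had 0 members at an unadjusted p under 0.05, among 10, 2 and 9 tested. The 25 testis and accessory gland markers (0.40, 0.28), of which 11 were tested, had 3, with Mst77F (at least 1.83-fold higher) among them. The 15 photoreceptor genes (-0.01, 0.749) also had 3, with the arrestin Arr2 at -0.85, inaE at -1.36 and rdgA at 0.97, and the 10 clock genes (0.17, 0.825) had 1, cwo (0.80). Mean and median differed in sign for the recognition proteins (median 0.03), the cell cycle genes (median 0.04) and the Turandot list (median -0.01), and camera ranked the mevalonate list below other genes although its mean was positive.

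By the size criterion that the labels name, 1146 probe sets were at least 2-fold higher and 511 at least 2-fold lower with JH III, so that 69.2% of them were higher. Of these, 959 and 452 had no overlap between the groups, which a choice by large difference between the same arrays favours. Among all probe sets tested 37.5% had no overlap, against 33.3% by chance with 2 arrays against 2. The split depended on the scaling, with 49.8% higher after quantile normalization (757 higher and 764 lower) and 40.1% after centring each array on its median (674 and 1005). The share higher also depended on dim probe sets. With the filter of 50% it was 58.6%, and with the pseudocount at the median of all values 57.9%. It was 61.4% without JH III replicate 1 (1051 and 661). The median log2 difference of all probe sets was 0.10 as deposited and -0.13 after centring. Relative to it, the antimicrobial peptide list stood at -0.79 and the respiratory chain list at -0.56 in both, and at -0.63 and -0.24 after quantile normalization.

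The arrays differed beyond the treatment. Across probe sets, the log2 levels of JH III replicate 1 correlated at 0.728 to 0.737 with the other arrays, which correlated at 0.835 to 0.863 among themselves. Its 18S ribosomal RNA signal was 5300, against 1964 in JH III replicate 2, 650 in acetone replicate 1 and 1705 in acetone replicate 2, although all arrays had been scaled to a trimmed mean of about 500. The ratio of 3' to 5' signal, a measure of RNA and target quality, also differed between the groups. For GAPDH it was 2.32 and 5.75 in the JH III arrays and 15.5 and 10.2 in the acetone arrays, and for eIF-4a 18.3 and 18.9 against 75.0 and 46.8. For actin it overlapped (3.40 and 16.7 against 35.6 and 14.2). Across the 4 arrays the GAPDH ratio ran in the reverse order of the hybridisation controls relative to the median probe set. The latter stood at 176 and 85.7 in the JH III arrays and 37.1 and 82.1 in the acetone arrays. The ratio therefore cannot be told apart from other differences between the arrays. All 4 arrays were scanned on 1 day, and acetone replicate 1 was the 1 array from another chip lot. Both acetone arrays were scanned before both JH III arrays, so that scan order and treatment cannot be told apart.

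**Figure D4:**
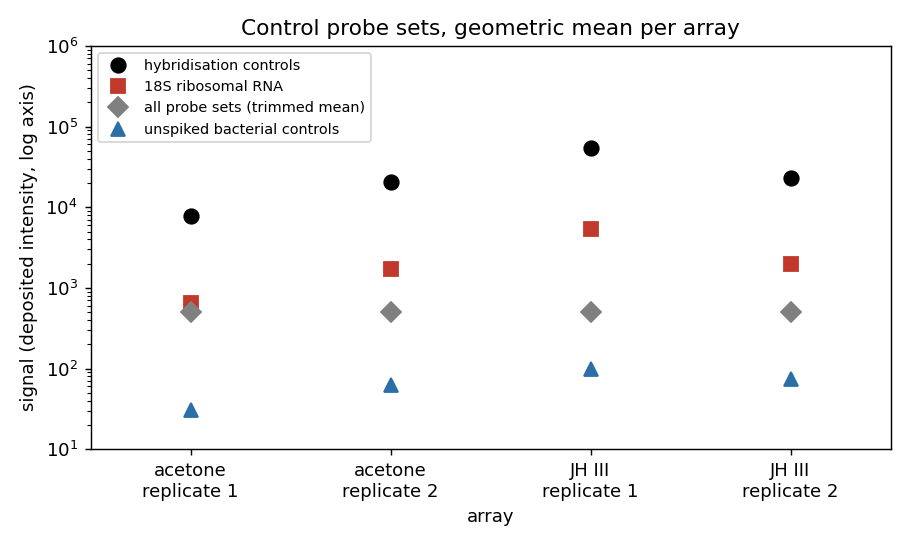
Geometric mean signal per array (linear intensity on a log axis) of the hybridisation controls, the 18S ribosomal RNA probe sets and the unspiked bacterial controls, with the trimmed mean of all probe sets for comparison. The hybridisation controls run from 7794 in acetone replicate 1 to 54170 in JH III replicate 1, while the trimmed mean stays at about 500.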

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

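The tests on the antimicrobial peptides without JH III replicate 1 and on fat body transcripts, both tests of RNA quality, the test of the respiratory chain list over other splits, and both tests of the 2-fold split were chosen after the results were seen; the remaining tests were set beforehand.

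Control probe sets, which enter no comparison, were higher in both JH III arrays than in both acetone arrays. The hybridisation controls, RNA added in fixed amounts, had a geometric mean of 54170 and 22915 in JH III replicates 1 and 2, against 7794 and 20718 in acetone replicates 1 and 2. The 18S ribosomal RNA probe sets stood at 5300 and 1964, against 650 and 1705. Unspiked bacterial controls stood at 97.48 and 75.12, against 30.3 and 62.1. With 2 arrays against 2, chance puts both arrays of one group above both of the other in 1 direction or the other for 33.3% of independent probe sets, and these controls move together.

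In the first pattern weighed, the lower level of the antimicrobial peptides, the list's median lay at percentile 0.18 of random lists matched on mean signal, and at 0 without JH III replicate 1. This argues against compression of bright signals as the whole cause. Of the 34 lists, however, 6 fell below the 2.5th percentile, 3 of them also without that array. Leaving out JH III replicate 1 left a mean of -0.74, which argues against that array alone. For a smaller share of fat body RNA as the whole cause, 6 fat body transcripts brighter than the trimmed mean would have to fall as far. Their median was -0.114 with all arrays (SE of their mean 0.254 over arrays) and 0.07 without JH III replicate 1 (SE 0.13 over genes). Both medians lay above the peptide list's means by more than 2 SE, the bound set. The SE over arrays rests on 2 residual degrees of freedom, however, and the 6 include the yolk protein transcripts Yp1, Yp2 and Yp3. The test therefore does not decide on fat body RNA as the whole cause or a part of it. Of the 3 splits of the arrays, 1 gave a list mean this large (-0.69, against at most 0.08 in size in the others), and 3 splits are too few for a share under 0.05. A response to the hormone, the biological explanation the design gives, may account for it and stays open beside scan order and RNA quality, which follow the treatment (the lowest acetone ratio of 3' to 5' signal of GAPDH was 1.78 times the highest JH III ratio), although within both groups the peptides were lower where that ratio was higher.

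In the second pattern, the lower level of respiratory chain genes, their median lay below all 10000 matched random lists, with all arrays and without JH III replicate 1 (percentile 0 in both), and without that array the mean was still -0.30, so neither signal-dependent compression between arrays nor JH III replicate 1 alone accounts for all of it. Compression may account for part, since the matched lists had a median of -0.23, against -0.54 for this list, and quantile normalization took its mean from -0.46 to -0.23 (camera adjusted p = 0.000933). Other variation between arrays stays open, since a split of the arrays that crosses the treatments moved the same list by 0.29 in size, against 0.46 in the real one, and gave 5 lists past the camera threshold with a preset correlation, against 4. A difference in RNA quality may account for it too. The list's mean level rose with the 3' to 5' ratio of GAPDH within both groups, though with 2 arrays in each. It also rose with that ratio between the groups (lowest acetone over highest JH III ratio 1.78). The GAPDH ratio ran in the reverse order of the hybridisation controls, so it cannot be told apart from other variation between arrays. A response to the hormone stays open and cannot be told apart from such variation.

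The third pattern is the excess of 2-fold higher over 2-fold lower probe sets. Centring each array on its median took the share of higher ones to 40.1%, but centring moves all probe sets of an array alike and so does not decide on the scaling to a common trimmed mean. Without JH III replicate 1 the share was 61.4%, too close to the bound of 60 set for it to decide on that array. Part of the excess lay in dim probe sets. The share was 58.6% with the filter of 50% and 57.9% with the pseudocount at the median of all values. The median difference ran from 0.57 in the dimmest of 10 classes of mean signal to -0.30 in the brightest. A response of many genes to the hormone was not tested separately.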

How the results depend on the processing

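The crossed replicate block was chosen after the data were examined; the other alternatives were planned. The antimicrobial peptide list kept its direction and its camera call in every refit for which the lists were tested (not the crossed block or the methods' t-test), with means from -0.92 (median centring) to -0.62 (quantile normalization), and lost the call at the same mean of -0.69 with an estimated correlation (adjusted p = 0.873) and with fry (adjusted p = 0.153). With an estimated correlation 0 other lists passed, against 3, at the same means of -0.30 for digestive enzymes, -0.36 for muscle proteins and -0.46 for respiratory chain genes, where the test rests on 2 residual degrees of freedom.

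The count of called probe sets was not stable. Against 17 (3 higher, 14 lower) it was 10 (8 lower) with the pseudocount at the median of all values, and 2, with 0 lower, under quantile normalization, median centring, no filter and the filter of 50%. It was 0 (0 higher, 0 lower) without a trend in eBayes, where 697 had an unadjusted p under 0.05, and 0 by the methods' t-test, with 607. The cause was not tested. The 2 probe sets called under quantile normalization, centring and both filters were all among the 17. Diedel passed in 11 of its 13 alternatives (adjusted p from 4.92e-27 to 0.802) with differences from 3.98 to 5.73. DptB passed in 3 of 13, with differences from -2.05 to -1.38 (adjusted p from 0.0069 to 0.948). All 11 called genes of the naming rule kept their sign in every alternative. Over 165 named genes and 2116 values, 10 gained a call, 0 reversed while called, and 38 uncalled values changed sign. Only the 11 called genes could lose a call, and of their values, under 13 alternatives each, 106 lost it.

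At least 2-fold higher and lower probe sets, 1146 and 511, became 1987 and 1028 with a pseudocount of 1, 213 and 155 with the median as pseudocount, 757 and 764 under quantile normalization, 674 and 1005 under median centring, and 510 and 360 with the filter of 50%. The 3 peptides lower adjusted over the list alone became 1 under quantile normalization and 0 without a trend and by the methods' t-test. Under quantile normalization 1 other list was lower and 1, the eggshell proteins, higher, while digestive enzymes (-0.25, adjusted p = 0.147) and muscle proteins (-0.24, 0.388) no longer passed. Without a trend muscle proteins did not pass (-0.36, adjusted p = 0.0503). With no filter 5 other lists were lower. The cause was not tested.

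Leaving out each array in turn, with the lone array assumed to vary like the other group, the count of called probe sets ran from 3 to 36, higher from 2 to 7 and lower from 0 to 29. It was 3 without JH III replicate 1 and without acetone replicate 1, 18 (7 of them among the 17) without JH III replicate 2 and 36 without acetone replicate 2. The 2-fold counts ran from 1051 to 2082 higher and 661 to 1238 lower, and the peptides lower adjusted over the list alone from 1 to 2. The peptide list's mean ran from -0.74 to -0.64, that of respiratory chain genes from -0.61 to -0.30, of digestive enzymes from -0.45 to -0.16 and of muscle proteins from -0.63 to -0.0947. Digestive enzymes and muscle proteins did not pass without JH III replicate 1 (adjusted p = 0.249 and 0.425) or acetone replicate 1 (0.114 and 0.792). Other lists called lower ran from 1 to 3 and higher from 0 to 1, the latter being the eggshell proteins.

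The labels do not say that a replicate number marks a shared day, and with 2 pairs it was not treated as a pairing: across probe sets the deviations of replicate 1 from replicate 2 in the groups correlated at -0.11. With the replicate block 2 probe sets were called (0 lower), and 1 peptide was lower adjusted over the list alone, while the 4 list calls held. With the crossed block the count was 109 (11 higher, 98 lower). A block for chip lot was not run, because acetone replicate 1 alone was on the other lot. Probe sets below the level of unspiked controls limit what these arrays can show of low genes.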

Other observations

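The families described here were chosen after the data were examined, and so were the tests on them.

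Maltases split disaccharides in the gut. The family was picked from the digestive list after the values of its members were seen, and was not tested against the rest of that list. The median of its 10 genes was -0.72 (SE 0.37, percentile 0.06 of matched random lists), and -1.0 without JH III replicate 1 (percentile 0). By limma 4 of them, Mal-A1, Mal-A4, Mal-A6 and Mal-A7, were lower adjusted over the family alone and 0 over all genes, while Mal-A8 was at 0.47 and Mal-B1 at 0.01. The Jonah serine proteases of the same list had a median of -0.39 (percentile 17.2) over 14 genes, and -0.03 without that array.

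The Npc2 sterol-binding proteins had a median of -0.92 over 8 genes (percentile 0 of matched random lists), and -0.47 without JH III replicate 1 (percentile 1.47). Npc2g fell over all genes and 3 members fell adjusted over the family alone, Npc2g, Npc2h (-1.37) and Npc2b (-0.99), while Npc2c was at 0.73.

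For odorant receptors the sign of the median depended on JH III replicate 1, and for gustatory receptors it did not. The median of 29 odorant receptors was 0.67 with all arrays (percentile 97.6) and -0.12 without JH III replicate 1 (percentile 7.61), and that of 15 gustatory receptors was 0.42 and 0.45 (percentiles 67.0 and 87.1). By limma 0 odorant and 0 gustatory receptors were called over all genes or adjusted over the family alone.

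For the count of probe sets past the threshold, the real split gave 17 and the highest other split 0, so that 1 of the 3 splits reached it. The splits are too few for a share under 0.05.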
